A study of Escherichia coli K-12 with 4 samples.

How the data were processed

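RNA sequencing of 4 libraries of Escherichia coli K-12 MG1655 was used, 2 from the wild type and 2 from a strain with the sigma factor gene rpoS deleted. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was stabilised in the culture, purified on columns that also remove genomic DNA, and made into libraries with a KAPA RNA Hyper Prep kit. The submitters' processing notes name Bowtie2 version 2.0.0, featureCounts and DESeq2, without their order or settings. The genome build, the annotation, the strand setting of the counting and any read filter are not given in the sources used here. Without the strand setting, reads of a gene and of an antisense partner cannot be told apart.

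The authors deposited 1 table for the series, with 4148 genes. It holds 1 column of TPM, reads scaled for gene length and library total, for each library, normalized by the authors so that each column sums to 1000000 over the listed genes. The same table holds the authors' log2 fold change of the deletion over the wild type, deposited as they computed it, whose sign was checked on rpoS. It also holds the authors' deposited p-values and q-values for that comparison, and the q-value is missing for 403 genes. Gene symbols and products were used as the table gives them. Of the 4148 gene identifiers, 4119 matched the RefSeq gene table of assembly ASM584v2, 29 did not, and 15 of the matched ones carry another symbol there. That table was used for coding lengths and for which genes neighbour each other, and no coordinates were taken from it. The deposited table has no rows for ribosomal, transfer or small RNAs, so nothing is said about them.

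TPM carries no depth of its own, so depth was estimated from the steps between low values. Multiplying TPM by the coding length plus 1 base gave whole multiples of 1 step for 100% of the values below 100 steps in each library, within a tolerance of 0.02 steps. With the coding length itself the share was 58.8% to 61.9%. Taking 1 step as 1 read gave totals of 4773341 and 4782204 reads in wild type replicates 1 and 2 and 5703009 and 7031081 in deletion replicates 1 and 2, over the genes with a matched length. A gene of the median coding length of 852 bp at 10 TPM then stands on 46.0 to 66.4 reads per library, so genes near that level carry the widest counting error.

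The test written before the data were examined foresaw counts or size-factor-scaled counts. Since the values are TPM, limma was applied to log2(TPM + 1) with a variance trend and robust empirical Bayes estimation, in limma version 3.58.1 with statmod 1.5.0 under R 4.3.3. Genes with a mean of at least 10 TPM over the 4 libraries were tested, which left 2995 genes and set 1153 aside. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. Genes past it are called higher or lower. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. An exact permutation test of a single gene with 2 libraries against 2 cannot give a p-value below 0.333, so each gene's p-value rests on the spread that limma pools across genes.

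A set of 20 gene lists was fixed from textbook knowledge before the data were examined. The lists cover RpoS-dependent stress genes, acid resistance, catabolism of GABA, glutarate and putrescine, curli and cyclic di-GMP, hydrogenase 1 with cytochrome bd-II, flagella, other sigma factors and regulators, ribosomal proteins, ribosome hibernation, the tricarboxylic acid cycle, amino acid biosynthesis, OxyR and SoxRS genes, heat shock, envelope stress, iron uptake, phosphate starvation, other sugars, anaerobic metabolism, the neighbours of rpoS and prophage genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and the rotation test fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. The listed genes gadY, appX, cheA, crl, clpB, gatC, intQ, dicB and stfE had no row under that name in the table.

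Named genes follow a rule fixed before the data were examined. It takes rpoS with its neighbours, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 TPM and no overlap between the groups. It also takes, for each list, up to 4 called members of at least 50 TPM with the largest absolute change, or the 2 members with the highest mean where none of those is called. For lists whose called members all lie below 50 TPM, and for single members that explain a count, genes were named after their values were seen, and the text says so.

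The procedure was tested on simulated data for this comparison. Values were drawn for 2965 genes with a replicate SD of 0.0671 on the log2 scale, and 200 genes were changed. It recovered 87.9% of the 1.5-fold, 98.4% of the 2-fold and 100% of the 4-fold changes. Of 197 calls, 14 were false (7.1%), none had the wrong sign, and 0 of 19 unchanged lists were called. Genes were drawn independently with 1 shared SD and as many rises as falls, unlike the data. That SD came from the median variance between replicates, so genes with a wider spread are not covered. The unchanged lists had no inter-gene correlation, so they do not check camera on lists whose genes vary together.

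Alternatives covered scaling by a trimmed mean of M values (TMM) on top of TPM, no filter and a minimum mean of 50 TPM, pseudocounts of 0.5 and 8, no variance trend, the replicate number as a block, each library left out in turn, a minimum absolute log2 change of 1 and the authors' deposited comparison. For the lists, members shared between lists were also removed. Added after the data were examined was limma-voom on the reads recovered from the TPM steps, for genes with a mean of at least 10 reads. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.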

Results

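The series belongs to a study of methods that rebuild bacterial transcriptional regulatory networks from ChIP-exo and RNA-seq, and this part measured the transcriptome with and without RpoS. RpoS is the sigma factor of the general stress response, which directs RNA polymerase to genes used in stationary phase and under stress. Escherichia coli K-12 MG1655, a laboratory wild type, and its rpoS deletion strain were grown with shaking at 37 °C in M9 minimal medium with 0.2% glucose and harvested at mid-exponential phase, at an optical density of about 0.6. Each strain is represented by 2 libraries, described as biological replicates. The labels do not say whether the cultures were started separately, so the p-values of single genes measure the spread between these samples. The camera p-values at the preset correlation set a list's genes against the other genes. Their size reflects the spread across genes rather than between samples. The libraries hold 4773341 and 4782204 recovered reads for the wild type and 5703009 and 7031081 for the deletion. Between 59 and 84 of the 4148 genes are listed at 0 in a library, and the 10 highest genes take 12.43% to 13.07% of the TPM, with lpp, the major outer membrane lipoprotein gene, first in all 4. Over the genes tested, the log2 values of replicates correlated across genes with r = 0.994 in the wild type and 0.995 in the deletion, and between strains with 0.932 to 0.936. Genes are not independent replicates, so these r describe the libraries only. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 4.77 in the wild type and 2.46 in the deletion.

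The targeted gene was examined first. The rpoS transcript (b2741) stood at 3937 ± 23.3 TPM (SD, n = 2) in the wild type, already abundant during exponential growth, and at 5.02 ± 1.44 TPM (SD, n = 2) in the deletion. This is a log2 fold change of -9.37 (SE 0.15, limma adjusted p = 2.68e-08). The remaining signal rests on 38 and 31 recovered reads, against 21107 and 21187 in the wild-type libraries. Of its chromosomal neighbours, nlpD (b2742), which encodes an activator of murein hydrolases and lies directly upstream, fell from 2153 ± 75.2 to 880.9 ± 3.08 TPM (SD, n = 2), a log2 change of -1.29 (SE 0.05, adjusted p = 1.06e-06). The other 6 tested neighbours had log2 values between -0.26 for ftsB and -0.10 for ispF and were not called, with adjusted p = 0.145 for pcm, 0.0597 for umpG, 0.232 for truD, 0.539 for ispF, 0.0740 for ispD and 0.173 for ftsB. The gene on the other side, ygbN, lay below the filter at 6.64 TPM in the wild type and 7.77 in the deletion. As a set, the 7 tested neighbours had a median log2 change of -0.22, or -0.10 without wild type replicate 2 (camera adjusted p = 0.0547, adjusted p = 0.496 with an estimated correlation and 0.0411 with fry). With 1 library left out the number called lower was 5 without wild type replicate 1, 2 without wild type replicate 2 and 3 without deletion replicate 1, against 1 with all 4. Without wild type replicate 1 the set test gave adjusted p = 0.0226.

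**Figure D1:**
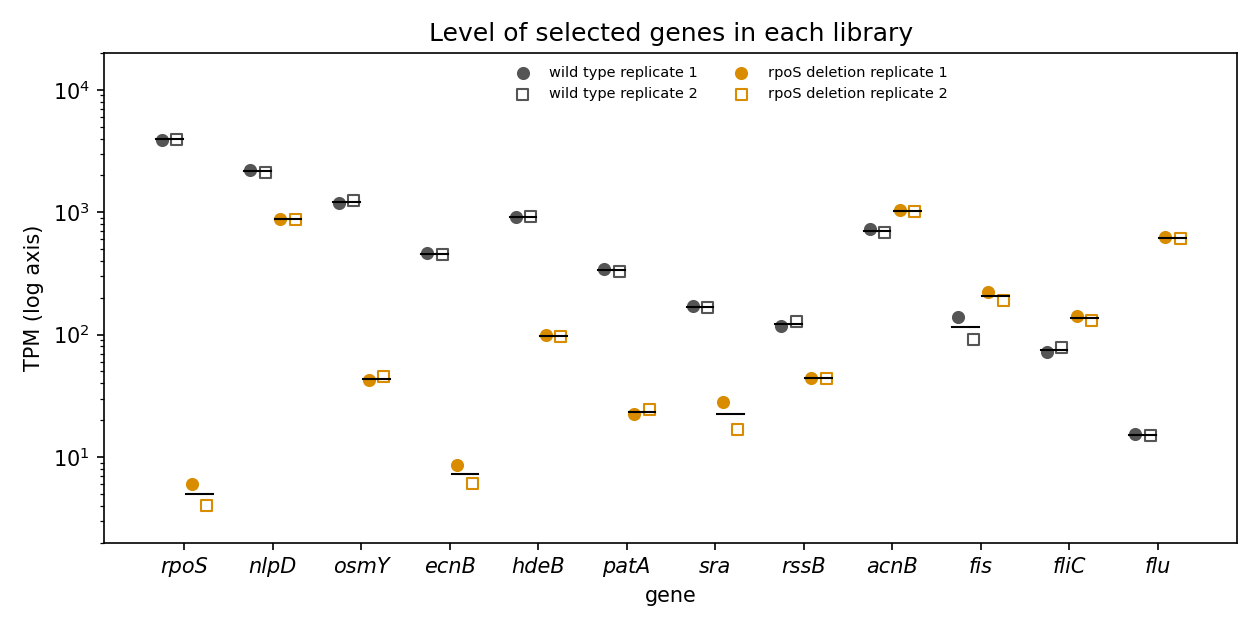
TPM (log axis) of 12 genes in each of the 4 libraries, with grey marks for the wild type, orange marks for the rpoS deletion and black bars for the mean of each pair. The rpoS marks fall from about 3937 to 5.02 TPM, while flu moves the other way, from 15.1 to 621 TPM.

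A large part of the exponential-phase transcriptome differed between the strains. Effects of the loss of RpoS and of the clone made into the deletion strain cannot be told apart here. Of 2995 genes tested, 532 were lower and 281 higher in the deletion, and 1147 had an unadjusted p under 0.05. The falls were larger than the rises. Among the lower genes 194 changed at least 2-fold, 108 at least 4-fold and 55 at least 8-fold, while 14 of the higher genes reached 2-fold and 3 reached 4-fold. The median log2 change was -0.71 among the lower genes and 0.37 among the higher genes. The lower genes together held 13.59% of the TPM in the wild type and 7.69% in the deletion, and the higher genes 21.72% and 27.45%. The values of the 2 strains did not overlap for 64.9% of the genes tested, against 33.3% by chance. Wild type replicate 2 lay below wild type replicate 1 for 67.3% of the higher genes, against 42.5% of all genes tested. In the authors' deposited table, 291 genes were higher and 387 lower at a q-value under 0.05, of which 243 and 361 were also called here in the same direction. Across 2994 genes the authors' deposited log2 values correlated with those computed here with r = 0.999. The number of higher genes was 174 without deletion replicate 2 and 148 without the variance trend, against 281, and that of lower genes was 335 at a mean of at least 50 TPM, against 532. Counts in the lists below refer to tested genes, and listed members of the table that were not tested lay below the filter of 10 TPM.

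**Figure D2:**
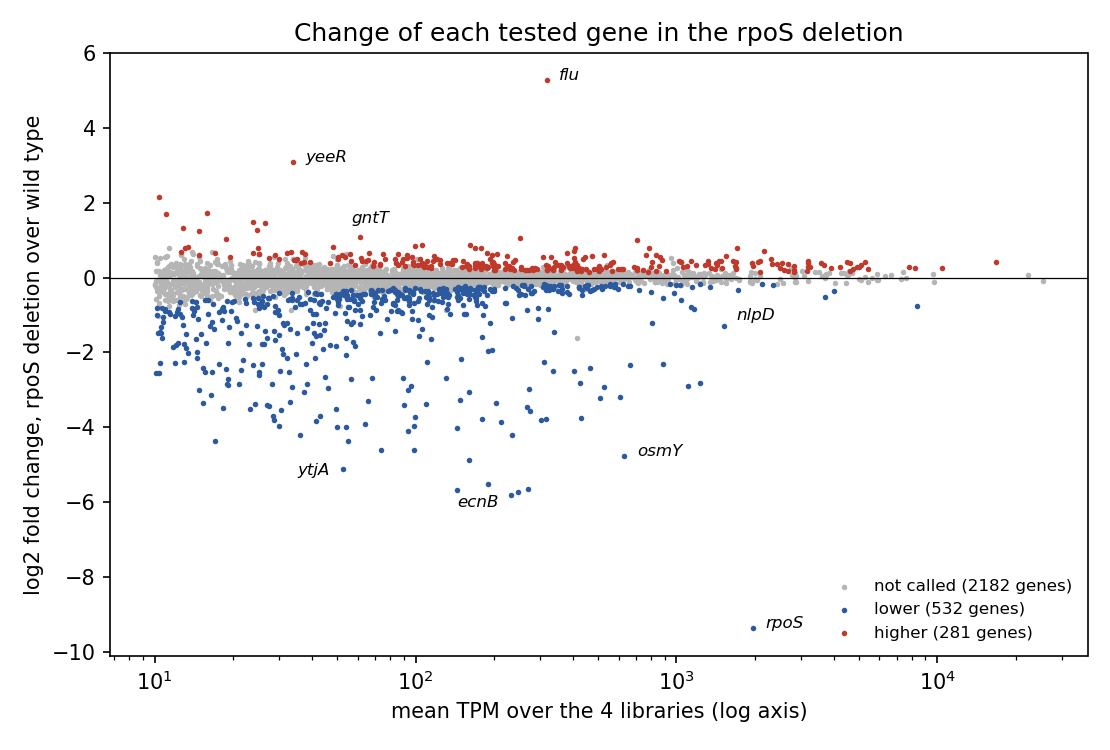
Mean TPM over the 4 libraries (log axis) against the log2 fold change of the rpoS deletion over the wild type for each of the 2995 genes tested, with 532 lower genes in blue, 281 higher genes in red and 2182 genes not called in grey. Falls reach further than rises, apart from flu at 5.27 and its neighbour yeeR at 3.08.

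Genes of the general stress response fell together. Of the 41 members of the list of RpoS-dependent stress genes in the table, 36 were tested, of which 35 fell and none rose, with a median log2 change of -2.94. Adjusted over the list alone the count was also 35. The largest falls in the list were those of ecnB, which encodes the entericidin B lipoprotein, from 458.3 ± 4.70 to 7.31 ± 1.74 TPM (SD, n = 2; log2 change -5.80, SE 0.15, adjusted p = 1.49e-07) and of ygaM, a gene of unknown function, from 485.9 ± 30.0 to 8.31 ± 2.42 TPM (log2 change -5.73, SE 0.17, adjusted p = 4.92e-07). The periplasmic chaperone gene osmY fell from 1219 ± 46.4 to 43.8 ± 1.87 TPM (log2 change -4.77, SE 0.06, adjusted p = 2.68e-08). The trehalose-6-phosphate phosphatase gene otsB, of the osmoprotectant trehalose pathway, fell from 142.7 ± 1.66 to 4.90 ± 0.59 TPM (log2 change -4.61, SE 0.14, adjusted p = 3.34e-07). The 1 member not called, xthA, named after its values were seen, encodes exonuclease III and stood at 257.2 TPM in the wild type and 256.0 in the deletion. The list was called as a set (camera adjusted p = 2.94e-28, fry adjusted p = 4.87e-05), with adjusted p = 0.113 with an estimated correlation.

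Acid resistance genes fell as well, all 12 that were tested out of 14 in the table, by a median of -2.98 on the log2 scale. Adjusted over the list alone, 12 were lower. The glutamate decarboxylase genes gadA and gadB changed by -4.11 (SE 0.13, adjusted p = 5.12e-07) and -3.97 (SE 0.12, adjusted p = 3.52e-07). These 2 genes are near-identical copies and may share reads, so their separate values are uncertain. The glutamate/GABA antiporter gene gadC changed by -3.30 (SE 0.12, adjusted p = 9.72e-07). For hdeB, a periplasmic acid chaperone gene, the level went from 920.0 ± 12.2 to 98.3 ± 2.73 TPM (SD, n = 2; log2 change -3.21, SE 0.05, adjusted p = 2.68e-08). The set was called (camera adjusted p = 4.81e-12, fry adjusted p = 0.00184), with adjusted p = 0.217 with an estimated correlation.

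Among the 10 largest falls named by the rule, those outside the lists, apart from rpoS, were ycaC, yiaG, yebV, yegP and ytjA. The putative hydrolase gene ycaC changed by -5.67 (SE 0.20, adjusted p = 1.01e-06) and the putative transcriptional regulator gene yiaG by -5.64 (SE 0.10, adjusted p = 2.68e-08). The genes yebV and yegP, which encode small proteins with domains of unknown function, changed by -5.52 (SE 0.11, adjusted p = 5.33e-08) and -4.88 (SE 0.13, adjusted p = 1.49e-07). The short gene ytjA stood at 104.2 and 99.0 TPM in the wild type and at 7.76 TPM in deletion replicate 1, and is listed at 0 in deletion replicate 2. Its change of -5.12 had an SE of 1.13 (adjusted p = 0.0439), and the call ended without wild type replicate 1 (adjusted p = 0.368) or wild type replicate 2 (0.386). In the authors' deposited table its q-value was 0.0947.

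In the catabolism of GABA, glutarate and putrescine, genes of different routes changed in opposite directions. Of 12 genes tested, out of 13 in the table, 6 fell, 4 rose and 2 were not called, with a median log2 change of -0.55. It was -1.29 with limma-voom on the recovered reads, where both the model and the filter differ. Adjusted over the list alone, 6 were lower and 5 higher. The 6 that fell include patA, which encodes putrescine aminotransferase and went from 336.5 ± 9.90 to 23.4 ± 1.44 TPM (SD, n = 2; log2 change -3.79, SE 0.09, adjusted p = 1.02e-07). The other lower members, named after their values were seen, were gabD, gabT, glaH, lhgD and patD, at -2.49, -2.31, -2.20, -2.30 and -1.22. All 4 members that rose belong to the puu genes for glutamylated putrescine, the other route of putrescine breakdown. They were puuA at 0.42 (SE 0.05, adjusted p = 0.00102), puuB at 0.36 (SE 0.10, adjusted p = 0.0369), puuE at 0.34 (SE 0.09, adjusted p = 0.0279) and, named after its values were seen, puuP at 0.41. The set as a whole was not called by camera (adjusted p = 0.444, adjusted p = 0.554 with an estimated correlation), while fry gave adjusted p = 3.39e-04 and camera on the authors' deposited table gave adjusted p = 7.93e-05. Camera's adjusted p was 0.0112 without deletion replicate 1 and 0.0143 without deletion replicate 2. The rises rest on small changes. The number of higher members was 2 without wild type replicate 1, 1 without deletion replicate 1 and 2 without deletion replicate 2. For puuB the adjusted p was then 0.0589 without wild type replicate 1 and 0.219 without deletion replicate 1, and for puuE it was 0.0781 and 0.131 without deletion replicates 1 and 2.

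Among genes for curli, cellulose and their control by cyclic di-GMP, 6 of the 10 tested fell and none rose, out of 15 in the table, with a median log2 change of -0.52. Adjusted over the list alone, 6 were lower. The curli secretion channel gene csgG changed by -0.44 (SE 0.10, adjusted p = 0.0176), with adjusted p = 0.0759 without deletion replicate 1. Larger falls, named after their values were seen, were those of mlrA, which encodes an activator of the curli regulator gene csgD, at -2.65, of the diguanylate cyclase gene dgcM at -2.51 and of the phosphodiesterase gene pdeR at -1.77. The regulator gene csgD itself stood at 12.1 TPM in the wild type and 14.2 in the deletion (adjusted p = 0.574). The set was called (camera adjusted p = 0.0327), with adjusted p = 0.366 with an estimated correlation, and the call ended without wild type replicate 2 (0.0775) or deletion replicate 2 (0.0562). In the list of hydrogenase 1 and cytochrome bd-II, a respiratory hydrogenase and a terminal oxidase, only 4 of the 9 genes in the table were tested, of which 3 fell and none rose. With limma-voom, where both the model and the filter differ, 6 were lower, and at a mean of at least 50 TPM none. Adjusted over the list alone, 4 were lower. The called members hyaD, appB and appC, named after their values were seen, changed by -0.98, -1.06 and -1.10, from levels of 17.0 to 20.3 TPM. The set had a median of -1.02 and a camera adjusted p of 0.0525 (adjusted p = 0.371 with an estimated correlation, 0.0160 with fry, 0.0322 with TMM scaling, 0.05 with limma-voom and 0.0106 without the filter on low values).

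Among the other sigma factors and the regulators of RpoS, 5 of 11 genes tested, out of 13 in the table, fell, 1 rose and 5 were not called, and adjusted over the list alone the counts were the same. The adaptor gene rssB, whose product delivers RpoS to proteolysis, went from 122.1 ± 7.49 to 44.3 ± 0.25 TPM (SD, n = 2; log2 change -1.44, SE 0.09, adjusted p = 2.65e-05). The envelope stress sigma factor gene rpoE changed by -0.47 (SE 0.05, adjusted p = 6.28e-04) and the heat shock sigma factor gene rpoH by -0.31 (SE 0.05, adjusted p = 0.00400). The stringent response cofactor gene dksA changed by -0.24 (SE 0.06, adjusted p = 0.0163), with adjusted p = 0.159 without deletion replicate 2. The RNA chaperone gene hfq, named after its values were seen, changed by -0.19. The member that rose, also named after its values were seen, was fliA, the flagellar sigma factor gene, at 1.47. Without wild type replicate 1 the higher members were 2. The vegetative sigma factor gene rpoD had a value of 0.13 (adjusted p = 0.119). As a set the list had a median of -0.19, or -0.07 without deletion replicate 1 (camera adjusted p = 0.340, adjusted p = 0.496 with an estimated correlation and 0.0160 with fry). Of the 4 ribosome hibernation genes, 2 fell, sra by -2.90 on the log2 scale (SE 0.22, adjusted p = 7.50e-05) and the ribosome modulation factor gene rmf by -0.37 (SE 0.04, adjusted p = 8.87e-04), the latter from 4512 ± 9.23 to 3495 ± 74.0 TPM (SD, n = 2). Adjusted over the list alone, 2 were lower and 1 higher, and the camera adjusted p was 0.292 (adjusted p = 0.496 with an estimated correlation and 0.0189 with fry).

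Flagellar genes rose. Of the 34 members of the list of flagella and chemotaxis in the table, 20 were tested, of which 11 rose and none fell, with a median log2 change of 0.79, and adjusted over the list alone 15 were higher. The filament gene fliC went from 74.9 ± 4.17 to 137.0 ± 8.82 TPM (SD, n = 2; log2 change 0.86, SE 0.09, adjusted p = 3.75e-04). Most members were expressed at a low level, with a median of 13.1 TPM in the wild type. Members named after their values were seen were the rod gene flgC at 1.73 and the hook gene flgE at 1.27. The master regulator genes flhD and flhC had values of 0.43 (adjusted p = 0.113) and 0.17 (adjusted p = 0.401) and were not called. The set was called (camera adjusted p = 7.95e-09, fry adjusted p = 0.00977), with adjusted p = 0.217 with an estimated correlation. The number of higher members was 18 without a filter on low values and 1 at a mean of at least 50 TPM. It was 20 with limma-voom on the recovered reads, where both the model and the filter differ.

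The largest rise was that of flu, which encodes the autotransporter adhesin antigen 43, from 15.1 ± 0.37 to 621.0 ± 17.3 TPM (SD, n = 2; log2 change 5.27, SE 0.08, adjusted p = 2.68e-08). All other rises among genes of at least 50 TPM were close to 2-fold or below it. The gluconate transporter gene gntT changed by 1.08 (SE 0.10, adjusted p = 2.01e-04) and the iron superoxide dismutase gene sodB by 1.05 (SE 0.11, adjusted p = 4.72e-04). The putative transporter gene yhjE changed by 0.85 (SE 0.15, adjusted p = 0.00601) and the fimbrial gene fimI by 0.80 (SE 0.09, adjusted p = 5.25e-04). The replication restart gene priB had a change of 1.01 (SE 0.19, adjusted p = 0.0125), the nucleoid protein gene fis one of 0.88 (SE 0.19, adjusted p = 0.0153) and the purine synthesis gene purA one of 0.79 (SE 0.17, adjusted p = 0.0198). These 3 calls ended when single libraries were left out. The changes stayed positive, and each gene's own spread then came from the remaining pair alone. Without deletion replicates 1 and 2 in turn, the adjusted p was 0.413 and 0.477 for priB, 0.291 and 0.218 for fis, and 0.0690 and 0.125 for purA. For purA it was 0.0566 without wild type replicate 1 and 0.205 without wild type replicate 2.

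Ribosomal protein genes rose by small amounts. Of 54 members, 24 rose, 3 fell and 27 were not called, with a median log2 change of 0.17, or 0.09 without wild type replicate 2 and 0.26 without wild type replicate 1. When adjusted over the list alone, 26 were higher and 3 lower. The wild-type libraries themselves differed in this group, where replicate 2 lay a median of 0.14 on the log2 scale below replicate 1, and 50 of the 54 genes were lower in it. The largest rises were those of rpsF at 0.80 (SE 0.19, adjusted p = 0.0288), rpsR at 0.72 (SE 0.19, adjusted p = 0.0406) and rplI at 0.61 (SE 0.12, adjusted p = 0.00787), which lie next to one another with priB. The rpmG gene changed by -0.60 (SE 0.10, adjusted p = 0.00381), from 1254 ± 33.1 to 834.3 ± 128.5 TPM (SD, n = 2). Some of these calls ended when 1 library was left out. For rpsF and rpsR this happened without either deletion replicate, and for rpsF also without wild type replicate 2. For rpmG it happened without either wild-type replicate. The changes kept their sign. Without deletion replicates 1 and 2 they were 0.915 and 0.684 for rpsF and 0.786 and 0.658 for rpsR. The rpsF change was 0.505 without wild type replicate 2, and that of rpmG -0.569 and -0.622 without wild type replicates 1 and 2. In such a fit a gene's own spread comes from the remaining pair alone. In the authors' deposited table the q-value was 0.0701 for rpsF and 0.112 for rpsR. The number of higher members was 38 without wild type replicate 1, 14 without deletion replicate 1 and 3 without the variance trend, and that of lower members was 1 without wild type replicate 1 or deletion replicate 2. The set was called by camera (adjusted p = 2.33e-07) and not by fry (adjusted p = 0.188), with adjusted p = 0.496 with an estimated correlation of 0.563.

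Genes of the tricarboxylic acid cycle also rose. Of 15 tested, 12 rose, 1 fell and 2 were not called, and adjusted over the list alone 14 were higher and 1 lower. The median log2 change was 0.42, or 0.32 without wild type replicate 2 and 0.43 without wild type replicate 1. Without the variance trend 6 rose. The 2 aconitase genes went in opposite directions. For acnB, the main enzyme of growing cells, the level went from 704.4 ± 29.3 to 1027 ± 9.24 TPM (SD, n = 2; log2 change 0.54, SE 0.05, adjusted p = 2.04e-04), and for acnA, the aconitase of stationary phase and stress, from 272.0 ± 5.08 to 170.1 ± 5.95 TPM (log2 change -0.67, SE 0.06, adjusted p = 2.07e-04). The 2-oxoglutarate dehydrogenase subunit gene sucB changed by 0.44 (SE 0.04, adjusted p = 3.33e-04). The succinate dehydrogenase subunit gene sdhC changed by 0.78 (SE 0.17, adjusted p = 0.0160), with adjusted p = 0.0972 without wild type replicate 1 and 0.288 without wild type replicate 2. The set was called (camera adjusted p = 8.14e-08, fry adjusted p = 0.0189), with adjusted p = 0.217 with an estimated correlation. Amino acid biosynthesis moved little. Of 45 genes, 7 rose, 4 fell and 34 were not called, with a median of 0.05 (0.10 with TMM scaling, 0.02 with limma-voom), and the counts adjusted over the list alone were the same. Examples are the arginine gene argD at 0.38 (SE 0.06, adjusted p = 0.00442), the histidine genes hisB at 0.36 (SE 0.06, adjusted p = 0.00561) and hisA at 0.32 (SE 0.08, adjusted p = 0.0300), and the S-adenosylmethionine synthase gene metK at 0.32 (SE 0.09, adjusted p = 0.0401). The calls of hisA ended without deletion replicate 1 (0.0784) and of metK without wild type replicate 2 (0.0933) or deletion replicate 2 (0.0769). That set was called by camera (adjusted p = 0.0138), with adjusted p = 0.301 with an estimated correlation, and lost its call without wild type replicate 2 (0.0549), deletion replicate 1 (0.0747) or deletion replicate 2 (0.0646). Its higher members were 13 without wild type replicate 1 and 3 without deletion replicate 2, and its lower members 2 and 1 without deletion replicates 1 and 2.

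**Figure D3:**
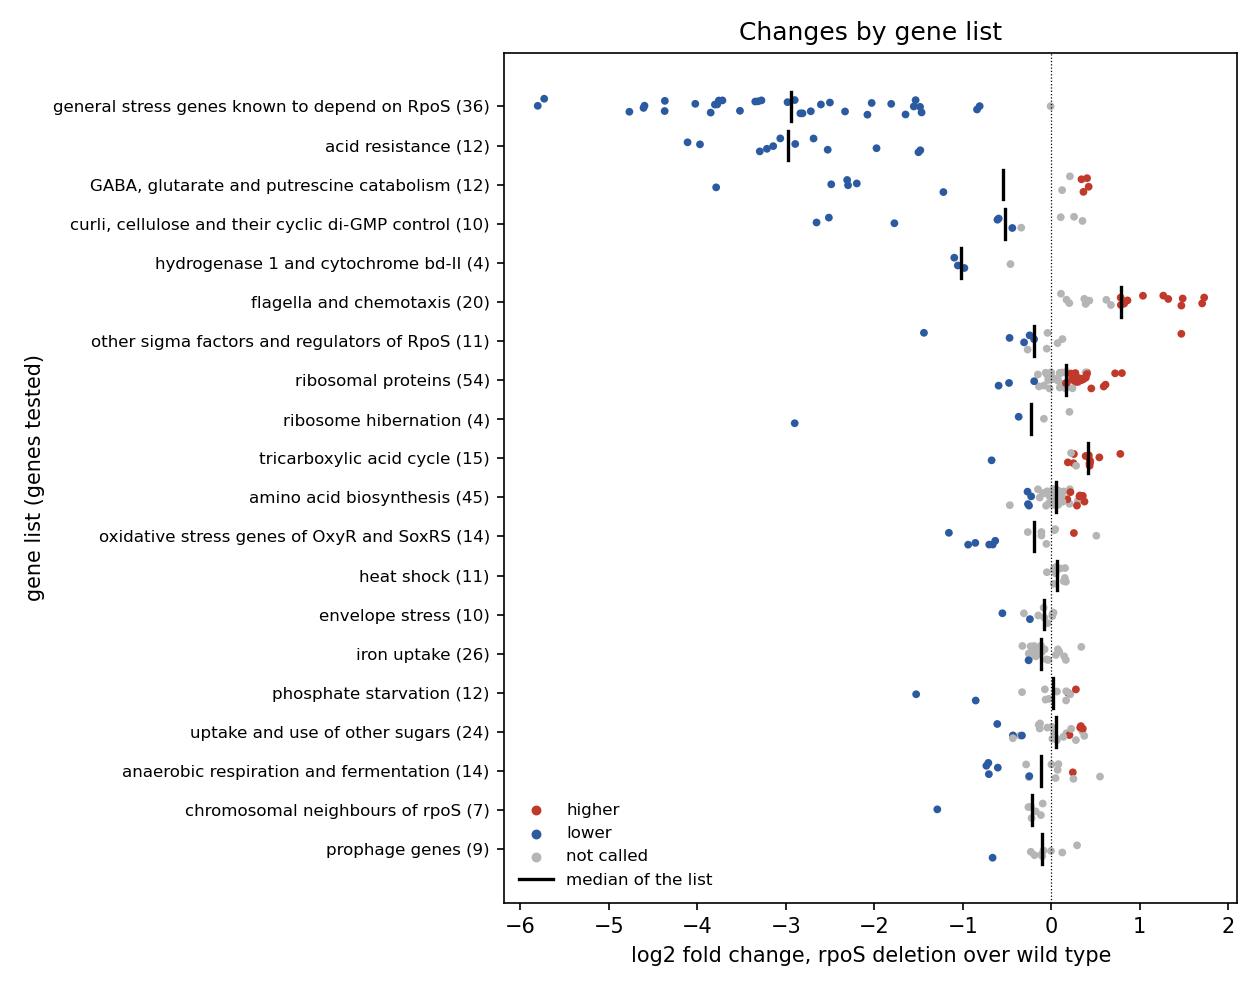
Log2 fold change of the rpoS deletion over the wild type for each tested gene of the 20 lists, with higher genes in red, lower genes in blue, genes not called in grey and the list's median as a black bar. The stress and acid resistance lists have medians of -2.94 and -2.98, while the flagellar list lies at 0.79 and the tricarboxylic acid cycle at 0.42.

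In the list of OxyR and SoxRS genes, which answer oxidative stress, 6 of 14 fell and 1 rose, and adjusted over the list alone 6 were lower and 2 higher. All 6 lower genes are suf genes, which encode the iron-sulfur cluster assembly system of stress and iron limitation. Among them sufA changed by -1.16 (SE 0.11, adjusted p = 2.26e-04), sufB by -0.86 (SE 0.09, adjusted p = 3.33e-04), sufD by -0.70 (SE 0.09, adjusted p = 0.00143) and sufS by -0.66 (SE 0.12, adjusted p = 0.00657). The member that rose, named after its values were seen, was the catalase gene katG at 0.26, and no member was called higher without deletion replicate 1, and 2 were without wild type replicate 1. The set had a median of -0.19, or from -0.35 to -0.10 with 1 library left out (camera adjusted p = 0.147, adjusted p = 0.455 with an estimated correlation and 0.0321 with fry). In the list of anaerobic respiration and fermentation, 5 of 14 tested, out of 17 in the table, fell and 1 rose, also when adjusted over the list alone. The fumarate reductase gene frdA went from 63.1 ± 1.43 to 37.6 ± 0.67 TPM (SD, n = 2; log2 change -0.73, SE 0.10, adjusted p = 0.00160), and the other frd genes, frdB, frdC and frdD, named after their values were seen, changed by -0.71, -0.70 and -0.60. The lactate dehydrogenase gene ldhA changed by -0.25 (SE 0.07, adjusted p = 0.0394) and the alcohol dehydrogenase gene adhE by 0.24 (SE 0.06, adjusted p = 0.0235), and without deletion replicate 2 their adjusted p was 0.297 and 0.140. Without wild type replicate 2 the higher members were 2. With TMM scaling ldhA was not called (adjusted p = 0.0775). The median of this list was -0.12, or from -0.25 to 0.03 with 1 library left out (camera adjusted p = 0.584, adjusted p = 0.639 with an estimated correlation and 0.0401 with fry).

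Further lists, fixed as signs of other stresses or nutrients, held few changes. None of the 11 tested heat shock genes was called, adjusted over all genes or adjusted over the list alone, and groL and dnaK had values of 0.05 (adjusted p = 0.468) and 0.03 (adjusted p = 0.685). That list passed camera as a set at a median of 0.06 (adjusted p = 0.0411; median 0.10 with TMM scaling and 0.03 with limma-voom), with adjusted p = 0.366 with an estimated correlation, 0.120 without wild type replicate 2, 0.247 without deletion replicate 1 and 0.184 without deletion replicate 2. Of 10 envelope stress genes 2 fell, also when adjusted over the list alone, and the anti-sigma factor gene rseA changed by -0.24 (SE 0.05, adjusted p = 0.0135). Without deletion replicate 1 rseA had adjusted p = 0.0764, and without either deletion replicate or wild type replicate 2 the lower members were 1. The other lower member, named after its values were seen, was the periplasmic chaperone gene spy at -0.55. Of 26 iron uptake genes tested, out of 29 in the table, exbD alone changed, by -0.26 (SE 0.06, adjusted p = 0.0137). It had adjusted p = 0.130 without deletion replicate 2, none of the list was called adjusted over the list alone, and without either wild-type replicate 3 members were lower. The medians of the envelope and iron lists were -0.08 and -0.12, or from -0.14 to -0.04 and from -0.15 to -0.08 with 1 library left out (camera adjusted p = 0.455 and 0.541, or adjusted p = 0.639 for each with an estimated correlation).

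Of 12 phosphate starvation genes tested, out of 17 in the table, 2 rose and 2 fell, also when adjusted over the list alone. The rises were those of phoH at 0.28 (SE 0.06, adjusted p = 0.0168) and the phosphate-binding protein gene pstS at 0.19 (SE 0.06, adjusted p = 0.0459). Without deletion replicate 2 the adjusted p was 0.130 for phoH and 0.174 for pstS, and pstS also had 0.248 without deletion replicate 1 and 0.0779 without wild type replicate 2. The falls, named after their values were seen, were those of the glycerol phosphate uptake genes ugpB at -1.53 and ugpC at -0.85, and 4 members were lower without deletion replicate 1. In this list the median was 0.02, or from -0.03 to 0.17 with 1 library left out. It was -0.10 with limma-voom, where both the model and the filter differ. The mean was -0.15, camera pointed up (adjusted p = 0.584, adjusted p = 0.639 with an estimated correlation) and fry pointed down (adjusted p = 0.146). Of 24 genes for other sugars tested, out of 35 in the table, 4 rose and 3 fell, also when adjusted over the list alone. The galactitol genes gatZ and gatA changed by 0.36 (SE 0.05, adjusted p = 0.00190) and 0.33 (SE 0.07, adjusted p = 0.0134), and the galactose genes galK and galM by -0.43 (SE 0.08, adjusted p = 0.00541) and -0.33 (SE 0.05, adjusted p = 0.00312). That list had a median of 0.05, or from 0.02 to 0.10 with 1 library left out (camera adjusted p = 0.238, adjusted p = 0.492 with an estimated correlation). Of 9 prophage genes tested, out of 18 in the table, 1 fell, intR, named after its values were seen, at -0.66, and none adjusted over the list alone. Without wild type replicate 1 the lower prophage genes were 4, and without wild type replicate 2 or deletion replicate 2 none was called lower. The prophage set had a median of -0.10, or from -0.24 to 0.03 with 1 library left out (camera adjusted p = 0.864, adjusted p = 0.945 with an estimated correlation).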

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

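The limma-voom alternative was chosen after the data were examined, and all others before. The planned count tools were not run, since the values are TPM. The log2 change of rpoS ran from -9.68 to -8.25 and it was called lower in each alternative. TMM scaling gave 355 higher and 453 lower genes, shifting the median by 0.048, and limma-voom on recovered reads gave 310 and 754. Higher genes numbered 148 without the variance trend, and 14 with an absolute log2 change of at least 1. Lower genes numbered 335 at a mean of at least 50 TPM, where 1968 genes were tested, and 194 with the minimum change. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 174 to 382 higher and 482 to 645 lower genes. The number of lists called, 8, became 5 at a mean of at least 50 TPM, where curli and flagella had fewer than 3 members left and were not tested, 0 with an estimated correlation, 14 with fry, and 5 to 9 with 1 library left out.

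With an estimated correlation the adjusted p of the 8 called lists was 0.113 for RpoS-dependent stress genes, 0.217 for acid resistance, 0.366 for curli, 0.217 for flagella, 0.496 for ribosomal proteins, 0.217 for the tricarboxylic acid cycle, 0.301 for amino acid biosynthesis and 0.366 for heat shock. That test estimates each correlation from 2 residual degrees of freedom. It also refers each list's statistic to those 2 degrees of freedom, which limits how small its p-values can be. With the preset correlation the degrees of freedom are about as many as the genes. The estimates were -0.0236 for RpoS-dependent stress genes, 0.00639 for curli, -0.0099 for amino acid biosynthesis and -0.0264 for heat shock. These lie below the preset 0.01, so a higher correlation does not account for the loss of those calls. That loss goes with the few degrees of freedom. For acid resistance, flagella and the tricarboxylic acid cycle the estimates were 0.0574, 0.0452 and 0.0499, and for ribosomal proteins 0.563. Ribosomal proteins had adjusted p = 0.188 with fry. With 1 library left out the range was 0.0289 to 0.0775 for curli, 0.0161 to 0.0747 for amino acid biosynthesis and 0.0473 to 0.247 for heat shock. Heat shock also had 0.0723 at a mean of at least 50 TPM, 0.0780 with limma-voom and 0.200 from the authors' deposited table. Beyond the role of those degrees of freedom, the cause of the changes named was not tested. Apart from these changes, the called lists stayed called in each alternative in which they were tested. None reversed in these. The variance trend of the gene tests does not enter camera as run here, so leaving it out says nothing about the lists.

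With the replicate number as a replicate block, 270 genes were higher and 561 lower. Same-numbered libraries deviated together with a correlation of only 0.03 over 2 pairs, so the numbers are not taken to pair the libraries. Under the block heat shock had adjusted p = 0.0781, and 7 of 61 called named genes other than rpoS lost their call.

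Of those 61 genes, none changed sign in any alternative. The calls lost were 17 without the variance trend, 8 in the authors' deposited table, 4 with limma-voom, 3 each without the filter and at a mean of at least 50 TPM, 1 each with TMM scaling and a pseudocount of 0.5, and 0 with a pseudocount of 8. Leaving out a library ended 5 without wild type replicate 1, 7 without wild type replicate 2, 11 without deletion replicate 1 and 13 without deletion replicate 2. Depth limits genes near 10 TPM, which rest on about 46.0 to 66.4 reads at median length.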

Other observations

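In this part the correlation of the ribosomal protein genes between the wild-type replicates and the deletion was chosen before its result was seen. The ribosomal set tests, the count with TMM scaling and the fit without wild type replicate 2 were chosen before the data were examined. Every other test was chosen after the result was seen, and genes named here were picked after their values were seen.

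Some genes outside the lists were looked at after their values were seen. In the operon of type 1 fimbriae, surface adhesins, 6 of 7 structural and assembly genes were higher in the deletion, with a median log2 change of 0.68 over the 7. The major subunit gene fimA went from 1252 ± 12.8 to 2146 ± 20.8 TPM (SD, n = 2; log2 change 0.78, SE 0.04, adjusted p = 1.49e-05), and the tip adhesin gene fimH had a value of 0.29 (adjusted p = 0.138). All 5 oligopeptide uptake genes oppA, oppB, oppC, oppD and oppF were called higher, with log2 changes of 0.36 to 0.67 and adjusted p of at most 0.0146. No enrichment was tested for the fim or opp genes, and strain and clone cannot be told apart for them. Among single genes that fell, the bacterioferritin gene bfr changed by -3.45, the glutathione hydrolase gene ggt by -3.42 and the ethanol dehydrogenase gene adhP by -3.38. The adjacent genes yqjC and yqjD, the latter for a ribosome- and membrane-associated protein, changed by -2.24 and -2.49.

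Of the 108 genes lower by at least 4-fold, 43 are in a list fixed beforehand and 65 in none. Genes with a y name, given to open reading frames before a function was assigned, made up 54 of the 108, 23.3% of the other genes tested and 29 of the 281 higher genes (10.3%). The odds ratio of 3.28 (95% interval 2.19 to 4.93) describes the same genes that prompted the comparison, so it tests nothing beyond them.

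The rise of flu extended to yeeR (6.33 to 61.2 TPM, log2 change 3.08) and yeeS (2.15), the next genes downstream. Extra copies of the region were tested on the 10 nearest tested genes, 5 on each side, whose median change was 0.011, with a range of -1.25 to 0.26. Among them insH6, insD3 and insC3 are insertion sequence genes that may share reads with other copies, so their values are uncertain. The others ranged from -1.25 for sbmC to 0.18 for dacD, which argues against a gain of a wider segment. A gain limited to flu, yeeR and yeeS was not tested. The closed sum of TPM leaves room for a rise of 0.095 on the log2 scale, far below the 5.27 of flu. Also open is whether the rise of flu follows from the loss of RpoS. A heritable on state of flu, a phase-variable gene, in the clone that was made into the deletion strain could also give it. Both deletion libraries have flu at nearly the same level (ratio 1.04), and strain and clone cannot be told apart with 1 deletion strain.

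The rise of ribosomal protein genes was weighed against 3 technical explanations. Their median change lay 0.217 above that of the other genes, which argues against the closed sum. With TMM scaling 25 members were called higher and the set had camera adjusted p = 1.27e-06. That scaling moved the median of all genes up by 0.048, and camera compares a list with the other genes. Neither the count nor the set test could thus have spoken for the closed sum. The set test itself is weaker than that 1.27e-06, with adjusted p = 0.496 with an estimated correlation and 0.188 with fry. Without wild type replicate 2, which has the lower ribosomal levels, 24 members were called higher, 23 of them among the 24 called with all libraries, and the set had adjusted p = 3.59e-05, at a median of 0.09. A variation between cultures or RNA preparations was tested by correlating, across the 54 genes, the difference between the wild-type replicates with the change in the deletion, which gave r = 0.532 (95% bootstrap interval 0.25 to 0.75). That r passed the limit set beforehand as a mark of such a variation. Both values use the wild-type libraries. With the change taken from wild type replicate 1 alone r was 0.25. That replicate then enters the compared values with opposite signs, which lowers r by construction, so this fall decides nothing. Over all genes tested, with both wild-type replicates in the change, r was 0.048. A reference of 10000 random sets of 54 from 400 other genes was added after r was seen. In these sets the median r was 0.38 (95% of sets from 0.13 to 0.67) and 18.3% reached that of the ribosomal genes. The 400 genes had only a lower limit on level, set near the lowest ribosomal genes, and were drawn singly. They were thus not matched to the typical ribosomal level. Against this reference r does not set the ribosomal genes apart, and such a variation and an effect of the deletion cannot be told apart here.

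The fall of nlpD was set against its operon. The genes umpG and pcm, transcribed with it from upstream, had a mean change of -0.202, which argues against lower transcription of the whole operon as the cause of the change of -1.288 in nlpD. The start site of the main rpoS transcript lies within nlpD, so reads of the rpoS leader count for nlpD, and a loss of those reads in the deletion strain could give this fall. Values per gene do not show where in nlpD the reads were lost, so this and a change of nlpD itself cannot be told apart here.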
